A study of Mus musculus with 36 samples.

How the data were processed

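RNA abundance was measured by bulk RNA sequencing in 36 libraries of RAW 264.7 cells, 3 per group in 12 groups. Total RNA was extracted with Trizol and libraries were made with Illumina TruSeq chemistry, per the labels' protocols. The authors trimmed reads with cutadapt and counted them per gene with featureCounts on mm10, per the submitters' processing notes. Versions, the aligner, the annotation release and the strand setting are not stated in the sources used here. The table of raw counts that the authors made holds whole numbers for 53465 Ensembl genes in 36 columns, 1 per library, with no scaling, per the file headers and the values. A second table by the authors gives FPKM values with gene symbols and biotypes, per the file headers. Its values were 0 exactly where the count was 0 and were proportional to the count over a per-gene length within each library, with a library constant of 0.940 to 1.24 times the count total. The FPKM values were not used for tests, and the symbols and biotypes were. Of the gene identifiers, 53274 (99.6%) matched GENCODE M21, from which mm10 positions were taken. Groups were taken from the labels of each library and left unchanged throughout.

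Totals were 4203313 to 7590271 counts per library. Of all genes, 17485 had 0 counts in every library. Mitochondrially encoded genes were not analysed here. Where all 3 libraries of a group had 0 counts, the fold change is given as a bound against 3 counts over the 3 libraries. For genes with 1 to 3 counts in a group only CPM levels are given, and medians of lists were also computed with genes at 0 set to their bound. Bounds and floors cover counting error only.

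Genes were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). The filter filterByExpr with the 12 groups kept 16988 genes, library sizes were scaled by TMM (factors 0.914 to 1.19), and a quasi-likelihood model with 1 mean per group was fitted to all 36 libraries (common dispersion 0.266). Fitting all groups together lets them share 1 estimate of the spread. Contrasts were LPS against solvent, each melatonin dose against solvent, each dose with LPS against LPS, the highest against the lowest dose with LPS, the interaction of LPS with 1 mM melatonin, the joint interaction over 5 doses, and the slope over log10 dose with and without LPS. Two-sided p-values were adjusted by Benjamini-Hochberg per contrast with a threshold of 0.05. CPM values use library sizes scaled by the TMM factors, and log2 CPM a prior count of 2. The comparisons, their tests, the gene lists and the alternatives were fixed before the data were examined, apart from the added alternatives named below and the tests of the 3 flagged patterns, which were chosen after the results were seen.

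Of 35 gene lists, 32 had at least 3 tested members and were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists of a contrast), again with an estimated correlation, and with fry. Within each list, p-values were also adjusted over the list alone. Genes named in the text were chosen by rule: the 10 highest and 10 lowest log2 fold changes per contrast among genes past the threshold with a mean of at least 5 CPM in the higher group and the 3 libraries of one group all above the 3 of the other, without Gm, Rik and unnamed genes, then up to 4 members per list with the smallest adjusted p, and always 12 genes of inflammation, oxidative stress and melatonin reception.

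The retained LPS response of a library was the slope of its log2 CPM differences from a solvent library on the LPS response, over 1362 to 1484 genes past the threshold that LPS changed at least 2-fold, in percent of the mean slope of the LPS libraries. It was computed 3 times, each time with 1 LPS and 1 solvent library kept out of the choice of genes and of the LPS response and used as the reference, and averaged. For single lists all tested members entered. Values measured from melatonin alone are the difference between the group with LPS and that without. The SDs of these 2 groups were added in squares, and the spread of the LPS-only libraries was left out. A common factor was tested per gene in the same model, as LPS with 1 mM melatonin minus melatonin alone minus the factor times LPS minus solvent, over members of 8 lists with Benjamini-Hochberg adjustment, in steps of 1%. Groups were compared by an exact permutation test over all 20 arrangements, two-sided, whose smallest p is 0.1, and the relation with log10 dose by a permutation test with 100000 resamples of single libraries. The 1 mM melatonin profile score is the same kind of slope, from the mean of the solvent libraries, on the difference between LPS with 1 mM and LPS with 0.1 µM melatonin, over 271 genes that passed there with at least a 2-fold change and that LPS did not move. Overlaps between comparisons that share control libraries were set beside 10 simulations of unchanged groups against the same libraries and beside the overlap of independent lists.

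The procedures named in this paragraph were tested on simulated counts for 16988 genes with known changes, with the spread of the solvent and LPS libraries. The joint interaction over 5 doses, the trend with LPS, fry, the common factor and the profile score were not tested in this way. For 1 mM melatonin against solvent, 7.46%, 32.8% and 36.4% of genes changed 1.5-fold, 2-fold and 4-fold were found, with 3.77% false among the calls. For 1 mM melatonin with LPS against LPS these shares were 4.48%, 16.4% and 40.9%, with 4.55% false. For the interaction they were 0%, 7.46% and 36.4%, with 11.1% false, and for the dose trend without LPS 11.9%, 35.8% and 45.5%, with 1.59% false. Camera found a changed list (adjusted p = 3.87e-07) and called 0 of 29 unchanged lists. The simulated genes varied independently of each other, so this does not test calls made under correlation between genes. A response set to 50% was recovered as 49.4% and an unchanged response of 100% as 99.0%.

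Alternatives were DESeq2 1.42.0 with its own size factors, edgeR with RLE size factors, no filter on low counts, a fit of only the compared groups, the replicate number as a block, and leaving out each library in turn (each replicate number for trends and the joint interaction). Leaving out a pair of doubted libraries and taking the weights of the retained response from all LPS and solvent libraries were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Functional terms beyond the fixed lists were not analysed here.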

Results

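RAW 264.7, a macrophage-like mouse cell line, was exposed to melatonin, to lipopolysaccharide (LPS, a component of the outer membrane of Gram-negative bacteria that triggers inflammatory signalling through Toll-like receptors) or to both. RNA was sequenced from 36 libraries in 12 groups of 3: solvent, LPS at 10 µg/mL, melatonin alone at 1 mM, 100 µM, 10 µM, 1 µM and 0.1 µM, and LPS with melatonin at each of those 5 doses. Cells that received both were given melatonin 30 min before LPS, and all cells were collected after 12 h of treatment. Between 4203313 and 7590271 reads were counted per library (median 6649250), with the lowest total in replicate 3 of LPS with 1 mM melatonin. At these depths, 3 counts correspond to 0.395 to 0.714 CPM (counts per 1000000 counted reads) in a single library, which is the level that a count of 0 still allows. Such floors cover counting error only. Of all counts, 70.9% fell in protein-coding genes and 20.4% in processed pseudogenes, so the levels of genes with near-identical copies, such as ferritin and ribosomal protein genes, are uncertain.

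Levels are given as the mean ± SD of CPM (n = 3 libraries per group), and changes as the log2 fold change ± SE from the edgeR quasi-likelihood test over 16988 genes, with Benjamini-Hochberg adjusted p-values. "Rose" and "fell" are used for genes past the adjusted threshold. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom from 8.95 to 37.7). The highest values were those of replicate 3 of LPS with 1 mM melatonin against replicates 1 and 2 (37.7 and 37.1, against 14.4 between those), and this library also had the highest TMM scaling factor (1.19, against 1.05 and 1.08). The first principal component held 21.8% of the variance and parted the libraries by LPS. It ran from -63.1 to -49.0 in libraries without LPS and from 65.5 to 67.6 with LPS alone, while LPS with 1 mM melatonin lay between, at 13.1 to 18.8.

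LPS alone was compared with solvent to ask how these cells respond to the inflammatory stimulus. Chemokines, cytokines, inflammatory enzymes and interferon-response genes rose together, and genes of mitosis and DNA replication fell. Ccl3 (chromosome 11, 83647844 to 83649355, mm10), a chemokine, went from 382 ± 11.7 CPM in solvent to 5579.9 ± 394 CPM with LPS, a log2 fold change of 3.87 ± 0.13. The cytokine gene Tnf rose from 173 ± 14.8 to 1248 ± 37.2 CPM (2.85 ± 0.15), and Il1b, which encodes interleukin 1 beta, from 1.36 ± 0.581 to 299 ± 29.3 CPM (7.75 ± 0.67). Il1a, Lcn2 and Il6 had 0 counts in all 3 solvent libraries and were at least 242-fold, 239-fold and 72.8-fold higher with LPS, each bound set by 3 counts over the 3 solvent libraries. Csf3 reached 188 ± 17.0 CPM and Nos2, the inducible nitric oxide synthase, 30.0 ± 2.05 CPM, both from 0.0999 CPM in solvent. In all, 2802 genes passed the threshold, 1427 higher and 1375 lower, and 1802 of them changed at least 2-fold.

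Among the gene lists fixed before the data were examined, 15 of 23 tested cytokines and chemokines rose and 0 fell (17 rose when adjusted over the list alone), with Ccl5 at 7.07 ± 0.38. Of 14 inflammatory enzymes and effectors, 12 rose and 1 fell. They included Acod1, which makes itaconate (8.14 ± 2.98 to 1452 ± 130.1 CPM), Ptgs2, the inducible cyclooxygenase (6.86 ± 0.45), and Saa3, an acute-phase protein (6.66 ± 2.56 to 564 ± 49.4 CPM). Interferon-response genes rose in 27 of 33 cases (31 adjusted over the list alone), with Irf7 at 5.33 ± 0.55, while Ifnb1 itself did not pass (0 ± 0 to 2.00 ± 2.68 CPM, adjusted p = 0.138). The NF-kB list held 13 genes that rose and 4 that fell of 22. Its inhibitors Nfkbia (1.76 ± 0.17) and Tnfaip3 (2.67 ± 0.28) were among the former. Of 27 NRF2 and antioxidant genes, 13 rose and 3 fell, with Slc7a11, the cystine importer, at 4.51 ± 0.22 and Hmox1, heme oxygenase 1, at 3.46 ± 0.28, while Nqo1 did not pass (0.209 and 0.0485 CPM). The unfolded protein and integrated stress response rose in 17 of 28 genes and fell in 1, and heat shock genes rose in 6 of 16 and fell in 1. Smaller groups also moved. Iron handling had 8 of 15 genes higher and 2 lower, antigen presentation 6 of 19 higher, Toll-like receptors and adaptors 6 of 24 higher and 2 lower, and the lysosome list 9 of 27 higher and 4 lower.

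Most tested members of the 2 proliferation lists fell with LPS, although larger single falls lay elsewhere, such as Cbfa2t3, with 0 counts in all 3 LPS libraries and at least 130-fold lower. Of 25 mitosis genes, 23 fell and 0 rose, with Mki67, the proliferation marker, dropping from 2259 ± 105 to 327 ± 19.7 CPM (-2.79 ± 0.13) and Top2a at -2.42 ± 0.16. Of 26 DNA replication genes, 22 fell, among them the helicase subunits Mcm6 (-2.86 ± 0.25) and Mcm5 (-2.25 ± 0.26). The list of histones and RNA-quality transcripts, which also holds nuclear RNAs such as Malat1, fell in 8 of 14 tested genes, among them the linker histone genes H1f0 (-1.64 ± 0.16) and Hist1h1e (-2.13 ± 0.22). Cholesterol synthesis and uptake fell in 12 of 25 genes, including Hmgcs1 (-1.09 ± 0.18), and LXR targets and fatty acid synthesis in 6 of 19, with 1 that rose. Immediate early genes split, 10 of 16 falling, with Fos at -3.37 ± 0.24 and Nr4a1 at -3.48 ± 0.30, and 5 rising, with Myc at 3.40 ± 0.36. The microglia and macrophage receptor Trem2 (-2.39 ± 0.20) and the Fc receptor Fcgr3 (-2.65 ± 0.23) fell, while the scavenger receptor Msr1 rose (3.88 ± 0.49). Camera, a test of a list against all other genes with a preset correlation between genes, called 18 of 32 lists, and 17 calls held with an estimated correlation. The respiratory chain list, with 8 of 26 genes lower, was the exception (adjusted p = 0.0701 with an estimated correlation).

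**Figure D1:**
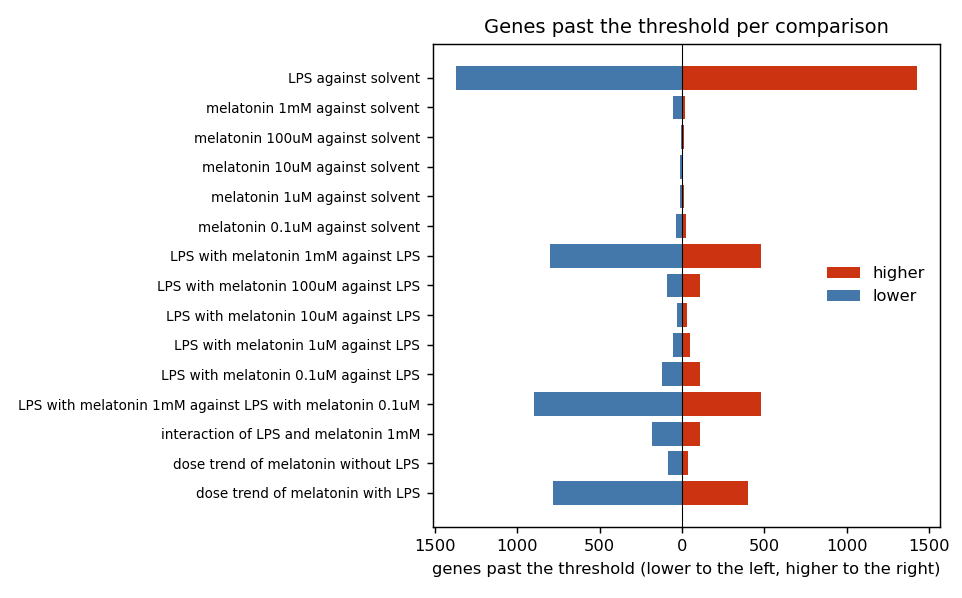
Number of genes past the threshold in each comparison, with higher genes to the right and lower genes to the left of 0. LPS alone moved 2802 genes and LPS with 1 mM melatonin 1282 against LPS, while melatonin without LPS moved between 14 and 71 against solvent.

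Melatonin without LPS was compared with solvent at each dose to see what it does to resting cells. At every dose Tnf, Nfkbia, Traf1 and Acod1 fell, genes that lie in or downstream of NF-kB signalling. Tnf went from 173 ± 14.8 CPM in solvent to 76.3 ± 9.20, 88.5 ± 9.40, 99.9 ± 4.96, 110.0 ± 20.8 and 96.5 ± 17.1 CPM from the highest to the lowest dose, and Nfkbia from 178 ± 40.0 to 74.3 ± 15.6, 81.0 ± 11.9, 79.2 ± 9.71, 91.1 ± 21.3 and 103 ± 15.7 CPM. Each of these 4 genes was lower in all 15 melatonin libraries than in the lowest solvent library. At 100 µM and 10 µM the calls of Tnf, Nfkbia and Traf1 held under every alternative run. At 1 µM that of Tnf was lost without melatonin replicate 1 (adjusted p = 0.0679) or 3 (0.227) or solvent replicate 1 (0.0926), 2 (0.190) or 3 (0.0709), and that of Traf1 without melatonin replicate 2 (0.106) or 3 (0.168) or solvent replicate 1 (0.131) or 2 (0.0971). Nfkbia was lost there without solvent replicate 1 (0.0806), and Acod1 without melatonin replicate 1 (0.0946) or solvent replicate 1 (0.0926) or 3 (0.155). At 0.1 µM Nfkbia was lost without melatonin replicate 2 (0.203) or 3 (0.113) or solvent replicate 1 (0.230) or 2 (0.0816), Traf1 without melatonin replicate 1 (0.0881) or 2 (0.0827), and Acod1 without melatonin replicate 1 (0.0687) or solvent replicate 3 (0.0526). At 1 mM Acod1 was lost without melatonin replicate 2 (0.0599). In fits of only the 6 compared libraries all 4 calls were lost at 1 mM (0.0652 for Tnf, 0.175 for Nfkbia, 0.226 for Traf1 and 0.483 for Acod1) and at 1 µM (0.535, 0.535, 0.535 and 0.695), and that of Acod1 also at 100, 10 and 0.1 µM (0.379, 0.0946 and 0.0720). No other gene passed at all 5 doses, and of 136 genes past the threshold at any dose, 106 passed at 1 dose only. Since the same 3 solvent libraries enter each comparison, part of that overlap may come from them. Unchanged groups simulated against these controls gave 0.04 calls per dose on average.

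At 1 mM, 71 genes passed, 17 higher and 54 lower. Myc fell from 6.24 ± 2.45 to 0.331 ± 0.222 CPM, and Gpr84, a receptor for medium-chain fatty acids, had a log2 fold change of -3.46 ± 0.56 and Slfn2 of -1.67 ± 0.26. Cytokines and chemokines fell in 4 of 23 genes (7 adjusted over the list alone), interferon-response genes in 3 of 33 (7 alone), NF-kB genes in 4 of 22 and unfolded protein response genes in 2 of 28 (6 alone). Those lists passed the camera test downward, as did mitosis (1 of 25 genes lower) and DNA replication (1 of 26 lower), and the NRF2 list passed upward with 1 gene higher and 1 lower. These 7 calls held with an estimated correlation and 5 did not: inflammatory enzymes, with 3 of 14 genes lower (adjusted p = 0.0560 with an estimated correlation), ribosome biogenesis (0.0753), macrophage identity (0.111), glycolysis (0.172) and osteoclast markers (0.172). The 1 mM libraries were unlike each other. A melatonin profile was taken from LPS with 1 mM against LPS with 0.1 µM melatonin, over 271 genes that LPS did not move. Replicates 1 and 2 of 1 mM melatonin alone showed 25.6% and 18.5% of it, and replicate 3 showed 6.94%. The count of genes was 347 without melatonin replicate 3, 20 without replicate 1 and 10 without replicate 2, and 41, 24 and 25 without solvent replicates 1, 2 and 3. A fit of only the 6 compared libraries gave 0 genes in edgeR, with 1169 at an unadjusted p under 0.05, whereas DESeq2 on all libraries gave 175.

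**Figure D2:**
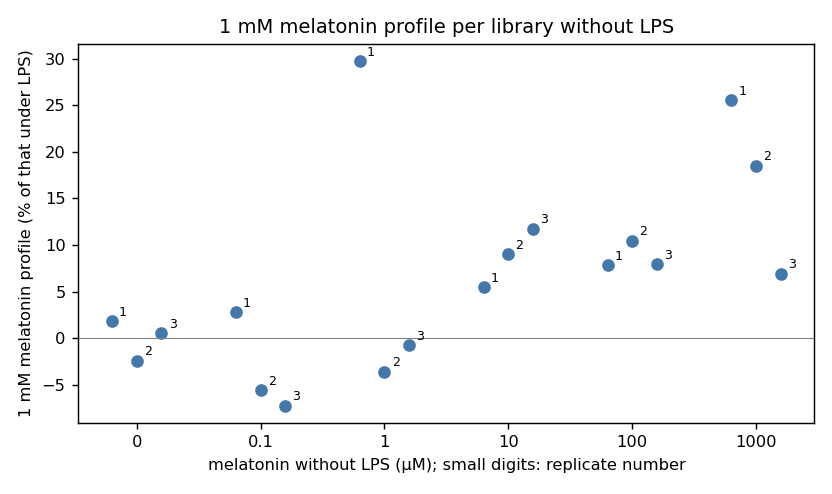
Score of the 1 mM melatonin profile in each library without LPS, as a percentage of the difference between LPS with 1 mM and LPS with 0.1 µM melatonin over 271 genes that LPS did not move, by melatonin dose with replicate numbers as symbols. Replicate 1 of 1 µM melatonin (29.7%) lay with replicates 1 and 2 of 1 mM melatonin, and replicate 3 of 1 mM (6.94%) lay with the 100 µM and 10 µM libraries.

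At the lower doses fewer genes passed in the edgeR fit of all libraries. At 0.1 µM DESeq2 gave 217 genes, against 175 at 1 mM. Fits of only the 6 compared libraries gave 338, against 0, so this order depended on the fit. At 100 µM 14 genes passed in the edgeR fit of all libraries, 10 higher and 4 lower. Of these 14, 10 were pseudogenes or genes known only by a Gm number. The 4 lower were those named above, with Traf1 at -1.95 ± 0.28 and Tnf at -0.97 ± 0.14. DESeq2 gave another balance, 16 higher and 15 lower. At 10 µM 14 genes passed, 2 higher and 12 lower, including the chemokine Cxcl2 (-1.49 ± 0.25), against 19 higher and 27 lower in DESeq2, and 9 without 10 µM replicate 2. Lars2 (-1.48 ± 0.31), protein-coding by its biotype, and the rRNA gene CT010467.1 (-1.46 ± 0.26) were among the lower. The share of counts in rRNA genes was 0.915% ± 0.228 in solvent and 0.343% ± 0.114 at 10 µM. Both genes also fell at 1 mM (log2 fold changes of -1.43 and -1.26, looked up after the values were seen). At 1 µM 25 genes passed, 11 higher and 14 lower (6 and 14 with the replicate number as a block, and 53 and 39 without replicate 3 of 1 mM and replicate 1 of 1 µM, whose labels are in doubt, an alternative chosen after the data were seen), with Phlda1 at -2.43 ± 0.41. That count was 66 without 1 µM replicate 1 and 3, 5 and 10 without solvent replicates 1, 2 and 3, and 0 when only the 6 compared libraries were fitted in edgeR (820 at an unadjusted p under 0.05), against 99 in DESeq2. At 0.1 µM 58 genes passed, 23 higher and 35 lower. Tnfaip3 fell (-1.79 ± 0.30), and 2 ferritin light chain pseudogenes rose, Ftl1-ps1 (1.03 ± 0.14) and Ftl2-ps (0.89 ± 0.16), whose reads cannot be told from those of their parent gene. Here the count was 27, 11 and 16 without melatonin replicates 1, 2 and 3, and 33, 28 and 17 without solvent replicates 1, 2 and 3.

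Gene lists moved at the lower doses too, although few members passed singly. Cytokines and chemokines were called lower by camera at all 5 doses and the NF-kB list likewise, and both calls held with an estimated correlation at each dose. The same 3 solvent libraries enter all 5 comparisons, so these calls are not independent, and a state shared by those libraries may be part of them. Cytokines had 1 member lower at 100 µM, 2 at 10 µM, 1 at 1 µM and 1 at 0.1 µM, and the NF-kB list had 2, 2, 3 and 4 lower, with 1 higher at 0.1 µM. The NRF2 list was called higher at 100 µM, 10 µM and 0.1 µM with an estimated correlation as well, with 0, 1 and 0 members past the threshold over all genes and 3, 3 and 4 when adjusted over the list alone. At 1 µM that call was lost (adjusted p = 0.0611 with an estimated correlation). Of the 14, 14, 12 and 9 lists that camera called from 100 µM to 0.1 µM, 9, 4, 6 and 4 held. Il6 and Nos2 were under 1 CPM at every dose without LPS, and Ptgs2 and Il1b did not pass at any. Neither melatonin receptor was tested, Mtnr1a having 1 count and Mtnr1b 2 counts over all 36 libraries, and the same held for Il10 with 10.

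Melatonin at 1 mM given with LPS was compared with LPS alone to ask whether it alters the inflammatory response. It lowered a large part of that response. Il1b fell from 299 ± 29.3 to 6.07 ± 4.55 CPM (-5.66 ± 0.58), Saa3 from 564 ± 49.4 to 13.2 ± 5.52 CPM (-5.44 ± 0.26) and Ptgs2 (chromosome 1, 150100031 to 150108227) from 836 ± 98.6 to 28.7 ± 16.2 CPM (-4.88 ± 0.40). Il6 had 0 counts in all 3 libraries, at least 71.1-fold below its 11.5 ± 4.18 CPM with LPS alone, and Nos2 fell from 30.0 ± 2.05 to 1.47 ± 1.33 CPM. Tnf fell less, from 1248 ± 37.2 to 652 ± 158 CPM (-0.94 ± 0.14), and Nfkbia did not pass (-0.50 ± 0.17, adjusted p = 0.0601, from 0.0175 to 0.230 over the alternatives). In total 1282 genes passed, 482 higher and 800 lower, 634 of them at least 2-fold.

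Cytokines and chemokines fell in 13 of 23 genes and rose in 1 (14 and 1 adjusted over the list alone), among them Csf3 (-5.56 ± 0.39), the interleukin 1 receptor antagonist Il1rn (-4.36 ± 0.41) and Ccl3 (-1.62 ± 0.12). Inflammatory enzymes and effectors fell in 11 of 14 and rose in 1, with the mitochondrial superoxide dismutase Sod2 at -2.06 ± 0.15 and the NADPH oxidase subunit Cybb at -2.23 ± 0.22. Interferon-response genes were lower in 6 of 33 cases (8 alone), including Zbp1 (-3.30 ± 0.50) and Oasl1 (-1.58 ± 0.26). The NF-kB list had 4 of 22 genes lower, such as Irak3 (-2.59 ± 0.21) and Nfkb1 (-0.97 ± 0.18), and 3 higher, among them Dusp1 (1.25 ± 0.19) and Zfp36 (1.12 ± 0.21), which encode a phosphatase and an RNA-binding protein that restrain inflammatory signalling. The receptors Cd14 (-1.81 ± 0.18) and Tlr13 (-1.71 ± 0.26) fell. Of 21 macrophage identity genes, 10 fell and 2 rose, and the scavenger receptors Msr1 (-4.83 ± 0.52) and Cd36 (-2.10 ± 0.22), the lectin Siglec1 (44.6 ± 6.86 to 0.532 ± 0.922 CPM) and lysozyme Lyz2 (-2.57 ± 0.32) were among those that fell, while Fcgr3 rose (1.80 ± 0.23). The NRF2 list had 6 genes lower and 1 higher of 27, with Slc7a11 at -2.26 ± 0.19 and Hmox1 at -1.92 ± 0.26. Its median was 0.05 and its mean -0.09, so the median and the downward camera call differ in sign. Unfolded protein response genes fell in 6 of 28 cases, including Asns (-0.80 ± 0.13), and lysosomal genes in 6 of 27.

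Some proliferation genes moved the other way. DNA replication rose in 5 of 26 genes (9 adjusted over the list alone), with Mcm6 going from 22.6 ± 8.57 to 64.4 ± 20.5 CPM, and mitosis in 3 of 25. Camera called both lists higher, and neither call held (adjusted p = 0.0684 and 0.238 with an estimated correlation). Glycolysis and hypoxia genes fell in 7 of 29 cases, among them Hk2 (-0.89 ± 0.17) and the glucose transporter Slc2a1 (-0.87 ± 0.17), and ribosomal protein genes fell in 5 of 24 and rose in 1, with calls that were lost likewise (0.0787 and 0.0684). The other 10 of 14 camera calls held, including the list of histones and RNA-quality transcripts, where 4 of 14 genes rose, the histone genes Hist1h1c (1.18 ± 0.23) and Hist1h2bc (1.47 ± 0.42) and the nuclear RNAs Malat1 (0.64 ± 0.13) and Neat1 (1.04 ± 0.24). Ighm, an immunoglobulin heavy chain gene, rose from 49.8 ± 17.9 to 235 ± 25.7 CPM after falling with LPS, and p53-related genes went both ways, with Ccng1 at 1.64 ± 0.25 and Mdm2 at -1.08 ± 0.16. A fit of only the 6 compared libraries called 558 genes. Without replicate 3 of LPS with 1 mM melatonin, which stood apart from its group, 1054 genes passed.

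**Figure D3:**
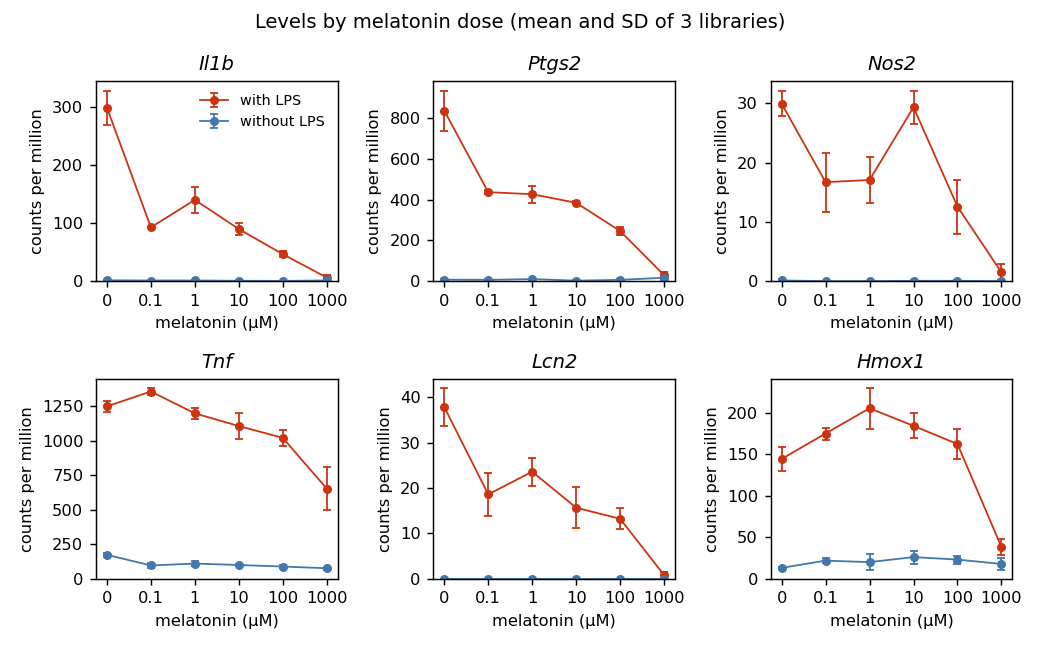
Levels of 6 genes in CPM by melatonin dose in µM, with LPS in red and without LPS in blue, as the mean and SD of 3 libraries. At 1000 µM with LPS, Il1b fell to 6.07, Ptgs2 to 28.7, Tnf to 652 and Hmox1 to 38.2 CPM.

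**Figure D4:**
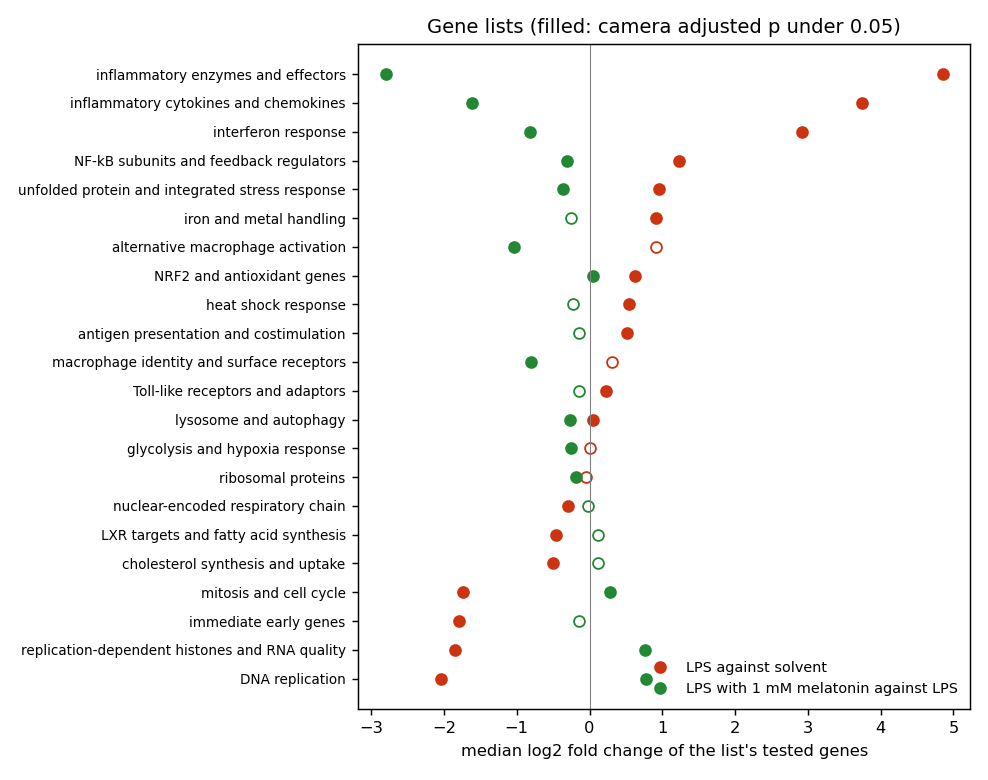
Median log2 fold change of the tested genes in each of 22 gene lists for LPS against solvent in red and for LPS with 1 mM melatonin against LPS in green, with genes at 0 in 1 group set to their bound and filled points where the camera test with the preset correlation passed. Inflammatory enzymes had a median of 4.85 for LPS against solvent and of -2.80 for LPS with 1 mM melatonin against LPS. Cytokines had 3.74 and -1.62.

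The lower doses of melatonin with LPS were compared with LPS alone in the same way. At 100 µM the inflammatory genes were lower again, by less. Il1b fell from 299 ± 29.3 to 46.5 ± 4.62 CPM (-2.69 ± 0.49, with an adjusted p of 0.253 in DESeq2), Ptgs2 to 246 ± 20.4 CPM (-1.77 ± 0.34), Csf3 to 48.5 ± 2.81 CPM (-1.96 ± 0.32), Saa3 to 234 ± 9.85 CPM (-1.27 ± 0.21) and Ccl3 to 3806 ± 187 CPM (-0.55 ± 0.11). Tnf, Nos2 and Il6 did not pass. In total 201 genes passed, 108 higher and 93 lower. Cytokines fell in 4 of 23 genes (8 adjusted over the list alone) and inflammatory enzymes in 3 of 14 (7 alone, with 1 higher). The interferon-response list was called lower with 0 of 33 genes past the threshold, and the NF-kB list with 2 of 22. The NRF2 list rose in 3 of 27 genes (6 alone), whereas 6 had fallen at 1 mM, and cholesterol synthesis had 1 of 25 genes higher. Osteoclast markers were called higher with 2 of 7 genes, including Nfatc1, a transcription factor also active in macrophages (1.31 ± 0.18), and Ocstamp, at 0 counts with LPS alone and at least 46.6-fold higher. Of 8 camera calls 7 held, the exception being DNA replication, with 3 of 26 genes higher (adjusted p = 0.074 with an estimated correlation). Lars2, protein-coding by its biotype, fell (-2.30 ± 0.32). The share of counts in rRNA genes was 0.242% ± 0.0489, against 0.631% ± 0.0842 with LPS alone. The count was 82 and 125 without replicates 1 and 2 of the 100 µM group and 115 and 121 without LPS replicates 2 and 3.

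At 10, 1 and 0.1 µM with LPS, 63, 104 and 231 genes passed, with 33, 50 and 111 higher and 30, 54 and 120 lower. Cytokines as a list were lower at 10 µM, with 0 of 23 genes past the threshold over all genes and 5 when adjusted over the list alone, and that was the single camera call of 6 that held. At 1 µM 0 of 3 calls held, and at 0.1 µM 1 of 6, the lysosome list, with 3 of 27 genes higher, among them the protease Ctsd (0.70 ± 0.14). Il1b, Ptgs2, Tnf, Nos2 and Il6 did not pass at these 3 doses. Of the inflammatory enzymes and effectors, Saa3 fell at 10 µM, from 564 ± 49.4 to 295 ± 8.90 CPM (-0.93 ± 0.21). Alox5 rose at 1 µM, from 0.0485 ± 0.0840 to 1.61 ± 1.21 CPM. Il1b stood at 89.8 ± 10.1, 140.1 ± 22.3 and 92.7 ± 0.114 CPM, against 299 ± 29.3 CPM with LPS alone. Inpp5k rose at 1 µM (3.47 ± 0.61) and 0.1 µM (3.24 ± 0.61), and had also risen at 100 µM (2.80 ± 0.61). Trem2 rose at 10 µM (0.93 ± 0.20) and 0.1 µM (1.16 ± 0.20), and had also risen at 100 µM (1.26 ± 0.20). The actin-binding protein gene Flna fell at all 5 doses (-0.75 ± 0.12 at 10 µM). Many calls lay in pseudogenes and Gm-numbered genes, as counted below. Lars2 fell by 2.44, 3.09 and 1.59 on the log2 scale at 10, 1 and 0.1 µM, and the rRNA gene CT010467.1 fell by 1.60 and 2.29 at 10 and 1 µM, while the share of counts in rRNA genes was 0.631% ± 0.0842 with LPS and 0.215% ± 0.0607, 0.130% ± 0.00662 and 0.410% ± 0.0677 at these doses. Pseudogenes and Gm-numbered genes made up 26 of 63, 49 of 104 and 90 of 231 calls.

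Counts at these doses moved when single libraries were left out. At 10 µM the count of 63 was 21, 17 and 31 without melatonin replicates 1, 2 and 3, and 40, 35 and 28 without LPS replicates 1, 2 and 3. At 1 µM the count of 104 was 64 and 50 without melatonin replicates 2 and 3, and 68 and 57 without LPS replicates 2 and 3. At 0.1 µM the count of 231 was 99 and 46 without melatonin replicates 1 and 2, and 124, 125 and 94 without LPS replicates 1, 2 and 3.

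Melatonin with LPS opposed the LPS response in most genes that both moved. Of 2802 genes past the threshold for LPS and 1282 for 1 mM melatonin with LPS, 781 passed both, and 750 of these (96.0%) moved in opposite directions, against 106 in independent lists of these sizes. The overlap comprised 459 genes that LPS raised and melatonin lowered and 291 that LPS lowered and melatonin raised. At 100, 10, 1 and 0.1 µM, 132, 30, 48 and 101 genes passed both and 114, 26, 37 and 72 were opposed, against 16.6, 5.19, 8.58 and 19.1 in independent lists. The LPS libraries enter both comparisons, with opposite sign, so part of the opposition may come from them, which independent lists ignore. Over all 2802 genes past the threshold for LPS, called or not with melatonin, 83.3%, 74.5%, 69.9%, 68.0% and 64.8% were opposed from 1 mM to 0.1 µM, while unchanged groups simulated against the same libraries gave 62.5% to 62.9%. These simulations gave 0 to 0.2 genes in both on average, and a covariance of the log2 fold changes of -0.198, against -0.574 observed at 1 mM and -0.290 at 0.1 µM. With a contrast that does not use the LPS-only libraries, LPS with 1 mM against LPS with 0.1 µM melatonin, 603 of 657 shared genes (91.8%) were opposed to the LPS response, against 114 in independent lists. That contrast called 1377 genes, 480 higher and 897 lower (885 without replicate 2 of LPS with 0.1 µM, and 542 when only its 6 libraries were fitted). Saa3 (-4.94 ± 0.25), Ptgs2 (-3.94 ± 0.39), Il1b (-3.97 ± 0.55) and Lyz2 (-2.89 ± 0.33) were lower at the higher dose, and Mki67 (1.11 ± 0.13) and Malat1 (1.32 ± 0.13), a nuclear RNA, were higher. Of the 1282 genes moved by 1 mM melatonin under LPS, 501 had not passed for LPS itself.

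The size of the LPS response that remained was measured per library over the genes that LPS moved at least 2-fold, with genes and weights taken from other LPS and solvent libraries than those measured. With LPS alone set to 100% ± 2.90, the response was 59.1% ± 2.02 at 1 mM, 83.1% ± 0.868 at 100 µM, 90.1% ± 0.474 at 10 µM, 91.9% ± 0.770 at 1 µM and 93.7% ± 0.799 at 0.1 µM. Each of these groups lay wholly below the LPS libraries, and the exact permutation test gave p = 0.1 for each, two-sided, the smallest that 3 against 3 libraries allow. The LPS-only libraries also stood apart from all libraries with both on the third principal component (-53.6 to -47.7, against -13.0 to 33.4), whatever the dose, so a state that these 3 libraries share may be part of the gap to LPS alone at every dose. Melatonin alone lay between -0.880% and 0.542%, with solvent at 0 by construction, but these values average genes that went both ways. At 1 mM alone, genes that LPS raised stood at -6.97% ± 4.72 and genes that LPS lowered at 10.1% ± 7.01. Across the 15 libraries with both, the retained response fell with the logarithm of the dose (Pearson r = -0.863, Spearman rho = -0.982). A permutation test over single libraries gave p = 1e-05 for each, the smallest that 100000 resamples give, and 1 relation was tested. Dose was given to whole groups, so this p takes the 3 libraries of a group as independent, which the labels do not say. The value of r lay between -0.879 and -0.805 when any 2 of the 6 libraries farthest from the median dose were left out. These omissions never removed a whole dose group, so they do not test how far r rests on 1 mM. Gene lists differed in what remained at 1 mM. Measured from solvent it was 31.6% ± 5.33 for inflammatory enzymes, 42.6% ± 5.34 for cytokines, 53.9% ± 7.46 for the NF-kB list, 57.0% ± 6.72 for DNA replication, 70.4% ± 5.14 for NRF2 genes, 71.1% ± 6.48 for interferon-response genes and 85.4% ± 4.28 for mitosis. Melatonin at 1 mM alone stood at -7.30% ± 6.92, -8.60% ± 3.00, -33.4% ± 6.11, 28.9% ± 26.6, 5.19% ± 2.08, -21.1% ± 5.54 and 20.5% ± 16.2 in the same lists, so its own effect enters these values and their order depends on the reference. Measured from melatonin alone, what remained was 38.9% ± 8.73, 51.2% ± 6.12, 87.3% ± 9.64, 28.1% ± 27.4, 65.2% ± 5.55, 92.2% ± 8.52 and 65.0% ± 16.8. All these SDs leave out the spread of the LPS libraries whose mean sets 100% in each list. The SDs of the LPS libraries were 3.87, 2.02, 9.63, 18.1, 1.31, 20.2 and 9.08 points in the same order. At 100 µM, NRF2 genes stood at 105.3% ± 1.31 and cytokines at 70.5% ± 4.28.

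**Figure D5:**
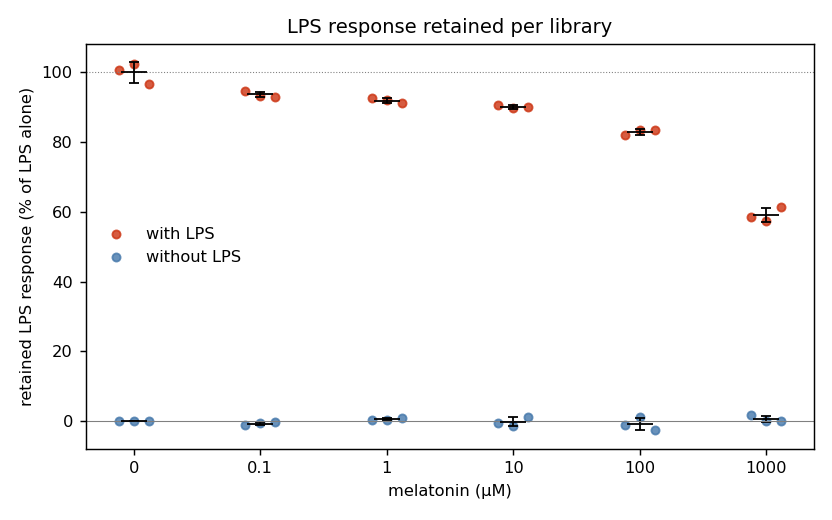
LPS response retained in each library, in percent of that with LPS alone, by melatonin dose in µM, with LPS in red and without LPS in blue, where black bars give the mean and SD of 3 libraries. The response with LPS ran from 93.7% at 0.1 µM to 59.1% at 1000 µM, and libraries without LPS stayed near 0, as an average over genes that went both ways.

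Trends over the 5 doses were tested as the change per 10-fold dose. With LPS, 1190 genes had a trend, 404 rising and 786 falling with dose. Saa3 (-1.06 ± 0.05), Csf3 (-0.99 ± 0.08), Il1b (-0.95 ± 0.12), Ptgs2 (-0.87 ± 0.08), Msr1 (-0.90 ± 0.11), Lyz2 (-0.63 ± 0.07), Tnf (-0.23 ± 0.03) and Hmox1 (-0.47 ± 0.06) fell with dose, and Pmaip1, a pro-apoptotic gene (0.69 ± 0.09), Mki67 (0.24 ± 0.03), Fos (0.37 ± 0.05) and Ighm (0.42 ± 0.04) rose. Cytokines fell in 12 of 23 genes, inflammatory enzymes in 11 of 14 with 1 that rose, macrophage identity genes in 13 of 21 with 1 that rose, NRF2 genes in 8 of 27 and lysosomal genes in 9 of 27. These slopes do not tell a graded fall from a step at 1 mM, and no trend was tested without that dose. From 0.1 µM to 1 mM with LPS, Ptgs2 stood at 436, 426, 384, 246 and 28.7 CPM. Hmox1 stood at 175, 205, 184, 162 and 38.2 CPM, below the 144 CPM of LPS alone at 1 mM only. NRF2 genes retained 104.4%, 103.2%, 95.9%, 105.3% and 70.4% of the LPS response measured from solvent, so their marked fall lay at 1 mM. Of 14 camera calls 11 held. Mitosis, DNA replication and osteoclast markers did not, with adjusted p = 0.0875, 0.154 and 0.154 with an estimated correlation. The count was 411 without replicate 2 of each group. Without LPS, 122 genes had a trend, 37 rising and 85 falling. The amino acid transporter gene Slc7a5 fell with dose (-0.21 ± 0.04), as did Myc (-0.78 ± 0.12, with an adjusted p of 0.169 when only the 15 libraries were fitted). Of 6 camera calls 0 held. The unfolded protein response list, with 4 of 28 genes falling, went to an adjusted p = 0.12 with an estimated correlation, and glycolysis, with 3 of 29, to 0.226. This count was 13 without replicate 2 of each group, and Tnf (-0.10 ± 0.03, adjusted p = 0.153, 0.0390 in DESeq2) and Nfkbia (-0.11 ± 0.04, adjusted p = 0.196) had no trend past the threshold in edgeR.

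The difference between the effect of 1 mM melatonin with and without LPS was tested as an interaction, with 287 genes past the threshold, 107 with a higher and 180 with a lower effect under LPS. The balance depended on the libraries, with 196 higher and 214 lower without the 2 libraries whose labels are in doubt and 47 and 55 in a fit of only the 12 compared libraries. Ptgs2 and Saa3, which melatonin lowered under LPS, had interactions of -6.07 ± 0.56 and -5.82 ± 0.36. Ccl3 (-1.42 ± 0.16), Sod2 (-2.28 ± 0.21), Irak3 (-2.57 ± 0.29), Msr1 (-4.25 ± 0.68) and Cd36 (-2.01 ± 0.31) also had lower effects under LPS than without it, as did the NRF2 genes Txnrd1 (-1.28 ± 0.18) and Hmox1 (-2.36 ± 0.37), and 0 of these 9 genes passed for 1 mM melatonin alone. Cytokines had 5 of 23 genes with a lower effect and 1 with a higher, inflammatory enzymes 4 of 14 and 1, and NRF2 genes 5 of 27 and 0. In the other direction, DNA replication had 7 of 26 genes with a higher effect under LPS (18 adjusted over the list alone), with Mcm6 at 2.46 ± 0.33, and mitosis 2 of 25 (8 alone), with Mki67 at 1.10 ± 0.18. Wee1 (3.97 ± 0.56), a kinase that holds back mitosis, and Prim1 (2.79 ± 0.58), a primase subunit, had higher effects as well. Of 12 camera calls 10 held, and macrophage identity (adjusted p = 0.292 with an estimated correlation) and ribosomal proteins (0.158) did not. For Tnf the effect did not differ past the threshold (0.25 ± 0.20, adjusted p = 0.67), nor for Nfkbia (0.76 ± 0.24, adjusted p = 0.107, from 0.0429 to 0.325 over the alternatives). The count was 466 in DESeq2 and 102 when only the 12 libraries of the 4 groups were fitted. Over all 5 doses jointly, 283 genes had effects that differed with and without LPS, with 678 in DESeq2, 75 without replicate 2 of each group and 168 without replicate 1.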

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

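The interactions, the retained response and the splits of the libraries were planned before the data were examined, and the tests of the 3 patterns below were chosen only after the results were seen. The effect of melatonin differed between cells with and without LPS in 287 genes at 1 mM and in 283 genes over 5 doses, by the test of the difference itself.

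For each comparison of 3 with 3 libraries, the 10 ways of splitting the 6 libraries are too few for a share under 0.05. In fits of the 6 libraries alone, the real split called 2932 genes for LPS (highest other split 0, 1 of 10 as large). For melatonin alone from 1 mM to 0.1 µM it called 0, 27, 62, 0 and 338 genes (highest others 1, 1, 0, 0 and 0), with 10, 1, 1, 10 and 1 of the 10 splits as large. For melatonin with LPS it called 558, 626, 374, 415 and 508 (highest other 0 each), and for 1 mM against 0.1 µM with LPS 542 (highest other 0), with 1 of 10 as large in each. For the interaction at 1 mM, 7 of 100 splits of the 12 libraries called as many as the real 102, the highest other 604, so these splits do not exclude chance. Of 99 other splits, 6 were as large, all among the 11 that part the LPS libraries by melatonin, and the 77 that part the libraries by melatonin in neither arm gave at most 0. The value of 604 was also the highest among the 12 that part the libraries without LPS by melatonin. A split that exchanges the melatonin labels in 1 arm only tests the sum of the 2 melatonin effects, not their difference. Splits that keep the melatonin effect under LPS can call genes with or without an interaction, so the share of 7 of 100 cannot decide between chance and an interaction. For the interaction over 5 doses 1 of 24 splits was as large as the real 283 (highest other 134), and for the trend with LPS 1 of 50 as the real 1179 (highest other 1). Both shares lie under 0.05 and are the smallest that these numbers of splits give. These splits shuffled single libraries over the groups of an arm, so a small share shows that those groups differ. It cannot tell an interaction from melatonin effects alike in both arms, nor a dose order from other differences between groups. For the trend without LPS 2 of 50 splits reached the real 92, the highest other being 102, a share under 0.05 by a narrow margin and with the same limit.

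Replicate 1 of 1 µM melatonin alone showed 29.7% of the 1 mM melatonin profile, while the other two 1 µM libraries showed -3.58% and -0.71%. An effect of 1 µM itself would raise those as well, and the higher of them, -0.71%, argues against it. Wrong labelling of replicate 1, or mixing with RNA of 1 mM cells, may account for its score of 29.7%, since no library outside the 1 mM group exceeded 11.8% and it correlated with the first 1 mM replicates at r = 0.33 and 0.30 across genes, near their own 0.37. An exchange with replicate 3 of 1 mM, which scored 6.94%, stays open: that library lay 9.08 points above the mean of the other 1 µM libraries, within a range of 9.54 taken from the pooled spread of the other groups without LPS (SD 3.38), by a narrow margin, but it did not correlate with them (r = -0.02 and -0.04, against 0.26 between those). The labels were kept, so effects of 1 mM melatonin without LPS may be understated, and leaving out both libraries gave 485 genes at 1 mM. Effects of 1 µM melatonin without LPS, and interactions that use these groups, may be understated or overstated. Of the 25 genes at 1 µM, 20 kept their call without both libraries, where 92 passed.

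Tnf, Nfkbia, Acod1 and Traf1 were lower at all 5 melatonin doses without LPS, in all 15 melatonin libraries against the lowest solvent library. An unusual single solvent library would not account for most of the 20 calls, since 15 held without solvent replicate 1 and 17 without either of the others. The cutoff of 15 was set after the results were seen. All 4 calls at 1 µM were lost without solvent replicate 1, so calls at all 5 doses do depend on that library. The scaling factors do not account for the falls, since they moved log2 fold changes by at most 0.0839, against a smallest fall of 0.66 ± 0.14. Fits of only the 6 compared libraries lost all 4 calls at 1 mM and at 1 µM. A state shared by the 3 solvent libraries, such as a difference in handling, cannot be told apart from an effect of melatonin down to 0.1 µM. The dose trend does not separate them: 0 of 4 genes had a falling trend past the threshold in edgeR (Tnf passed in DESeq2, adjusted p = 0.0390), which an effect that grows with dose would give and an effect saturated at the lowest dose would not.

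At 1 mM melatonin with LPS, the retained response differed between gene lists, and their order changed with the reference. It ran from 31.6% for inflammatory enzymes to 85.4% for mitosis when measured from solvent. Measured from melatonin alone, it ran from 28.1% ± 27.4 for DNA replication to 108.5% ± 18.9 for the unfolded protein response. These SDs leave out the spread of the LPS-only libraries, with SDs of 18.1 and 9.28 points in these lists. The place of DNA replication is uncertain, since the libraries with 1 mM melatonin alone ran from -1.63% to 46.6% in that list. A common factor on the log2 scale, such as a weaker LPS stimulus that lowers all of the response alike, added to the effect of melatonin alone, does not by itself account for it. The test takes solvent and LPS alone as they stand, and a state shared by the libraries of either group would give departures as well. Over factors from 0 to 100%, at least 37 of 198 tested members of the 8 lists departed past the threshold (fewest at 67%, and 48 of 199 without the doubted 1 mM library). At that factor 5 of 14 inflammatory enzymes kept less of the response and 1 more, while 7 of 33 interferon-response genes and 4 of 28 unfolded protein response genes kept more and 0 less. Measured from melatonin alone, the unfolded protein response also stood at 111.8%, 106.8%, 122.8% and 107.2% from 100 to 0.1 µM, and interferon-response genes at 96.5%, 111.2%, 102.5% and 102.3%. All genes that LPS moved at least 2-fold stood at 83.9%, 90.4%, 91.5% and 94.4%. At 1 mM the 3 means were 108.5%, 92.2% and 58.5% in the same order, so the gap of both lists to all genes was widest there. Single members were tested against a factor at 1 mM only. Whether those that kept more show an effect particular to 1 mM therefore stays open. Cytokines and chemokines went both ways, with 3 of 23 genes that kept less and 4 more, the NF-kB list had 2 of 22 less and 6 more, and NRF2 genes 2 of 27 less and 0 more, so inflammatory genes did not move as a block. For mitosis and DNA replication, with 1 of 25 and 2 of 26 genes that kept less, a difference from the common factor stays open. The low depth of replicate 3 of LPS with 1 mM does not account for it either, since 42 of 199 members departed without that library. An effect of melatonin on some LPS-responsive genes more than on others is a hypothesis that stays open, and neither a weaker stimulus to which genes respond unequally nor a response slowed in time was tested, since cells were collected at 1 time point and 1 LPS dose.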

How the results depend on the processing

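Leaving out 2 libraries whose label is in doubt (replicate 3 of 1 mM and replicate 1 of 1 µM melatonin alone) and weights from all LPS and solvent libraries were chosen after seeing the data, and the cause of a change was not tested unless stated. No value of a named gene or list reversed. The larger side of the higher and lower genes did turn: for LPS, 1548 higher and 1582 lower in DESeq2 and 1372 and 1402 with RLE size factors, with no filter 17 and 23 at 100 µM without LPS and 63 and 66 at 10 µM with LPS, without the 2 libraries 53 and 39 at 1 µM without LPS and, with LPS, 120 and 119 at 1 µM and 186 and 175 at 0.1 µM, and with only the compared groups 279 and 347, 145 and 229 and 256 and 252 at 100, 10 and 0.1 µM with LPS. Genes with few counts limit all settings: 3 counts equal 0.395 to 0.714 CPM per library. RLE size factors and the replicate block moved no total count of genes by more than 1.5 times, though with the block the higher genes at 1 µM without LPS went from 11 to 6. Of 861 values of named genes, 849 kept their side of the threshold with RLE size factors, 814 of 821 with DESeq2, 801 with no filter, 823 with the block, 834 without the 2 libraries, 588 of 808 in fits of only the compared groups and 3945 of 5135 over the omissions of a library. Of 480 tests of lists, 64 lost their call with an estimated correlation, 2 lost and 1 gained it with the block, while fry lost 30 and gained 35 calls in its directional form and lost 38 and gained 121 in its mixed form.

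In the order 1 mM, 100, 10, 1 and 0.1 µM, genes past the threshold without LPS numbered 71, 14, 14, 25 and 58. DESeq2 gave 175, 31, 46, 99 and 217, no filter on low counts 151, 40, 49, 89 and 137, only the libraries of the compared groups 0, 27, 62, 0 and 338, and the fit without the 2 doubted libraries 485, 24, 43, 92 and 155. The edgeR fits with 0 genes had 1169 and 820 at an unadjusted p under 0.05. With LPS, 201, 63, 104 and 231 genes from 100 to 0.1 µM became 391, 166, 293 and 459 in DESeq2, 626, 374, 415 and 508 with only the compared groups, and 352, 137, 239 and 361 without the 2 libraries. No filter gave 308, 129 and 187 from 100 to 1 µM. Only the compared groups gave 558 at 1 mM with LPS against 1282, 542 for 1 mM against 0.1 µM with LPS against 1377, and 102 for the 1 mM interaction against 287, where DESeq2 gave 466. The interaction over 5 doses (283) gave 678 in DESeq2, 609 with no filter and 466 without the 2 libraries. The trend without LPS (122) gave 340, 263 and 816. Opposed genes fell from 37 to 22 at 1 µM and from 72 to 43 at 0.1 µM with a log2 fold change of at least 1, which tests fewer genes. Weights from all libraries gave a retained response of 56.8%, 77.1%, 83.0%, 84.5% and 85.2%, since noise in the LPS libraries then enters their own weights.

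Leaving out 1 library gave 2280 to 2369 genes for LPS. Without LPS the ranges were 10 to 347 at 1 mM, 14 to 16 at 100 µM, 9 to 14 at 10 µM, 3 to 66 at 1 µM and 11 to 33 at 0.1 µM. With LPS they were 918 to 1166, 82 to 134, 17 to 40, 50 to 81 and 46 to 221. They were 885 to 1359 for 1 mM against 0.1 µM with LPS and 209 to 320 for the 1 mM interaction. Leaving out a replicate number gave 75 to 218 for the interaction over 5 doses, 13 to 174 for the trend without LPS and 411 to 1063 with LPS. Only replicate numbers link libraries across groups. Libraries with the same number had a mean correlation of deviations of -0.00155, 11 of 36 correlated best with their own number, and 0 of 12 compared pairs of groups had all 3 correlations over 0.1, so no pairing was established. With the block, 2779 genes passed for LPS against solvent and 1241 for 1 mM melatonin with LPS.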

Other observations

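The values in this part were chosen after the results were seen. Under LPS, 5 genes rose at all 5 melatonin doses: Ifi30, a lysosomal thiol reductase, Aes, Tmem50a and the ferritin pseudogenes Ftl1-ps1 and Ftl2-ps. Another 12 fell at all 5 doses: the cytoskeletal genes Flna and Dst, the RNA-binding protein gene Hnrnpf, the processed pseudogene Pgk1-rs7, and genes known only by a Gm number or a Rik name. Of 1482 genes past the threshold at any dose with LPS, 1251 passed at 1 dose only and 231 at 2 or more. Pairs of doses shared 17 to 55 higher and 16 to 59 lower genes. Unchanged groups simulated against the same LPS libraries gave 0.1 calls per dose on average and shared at most 1 gene, so the random spread of these libraries does not give the overlap. The simulations do not cover a state that the 3 LPS libraries share.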
